A study of Mus musculus with 4 samples.

How the data were processed

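H2A.Z, a variant of the core histone H2A that marks promoters and other regulatory sites, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic fibroblasts that were wild type or knockout for Anp32e, a histone chaperone of H2A.Z. Per the labels' protocols, heterozygous mice were crossed, and each culture was started from the torso of a single embryo collected at embryonic day 10.5. Per the labels, they were on a C57BL/6 background and between passages 5 and 10. Chromatin was sonicated, and libraries were read as single-end reads of 50 bases. The labels give 1 H2A.Z library and 1 input library per genotype, 4 libraries in all. The input libraries had no file and were not analysed here.

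The authors deposited 1 peak list for each of the 2 H2A.Z libraries. Each list has 3 columns, the chromosome, start and end of every peak. Per the file headers, the lists were saved from Galaxy, a web platform for sequence analysis. Per the submitters' processing notes, the genome build was mm9 and the tools were CASAVA 1.8.2, Bowtie 0.12.8, MACS 1.4.2 and HOMER. The role, order and settings of those tools, the threshold of the peak calls and the use of the inputs are not given in the sources used here. Peaks within a list did not overlap one another. The lists hold no height, fold enrichment, p-value or read count per peak, so the depth of the libraries is unknown and H2A.Z signal within a peak could not be compared. Peak calls depend on depth, on fragment length and on the threshold, and a deeper or more enriched library usually gives more and wider peaks.

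Everything reported was computed from peak positions in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9. Coordinates are printed on mm9 and count from 1. A peak was called shared when it had at least 1 bp in common with a peak of the other list, counted from each side. Chance overlap was described by 100 circular shifts of a list within each chromosome, and chance distances by the shifted one-genotype peaks that overlapped no peak of the other list. Matched pairs were peaks that overlapped exactly 1 peak of the other list in both directions. For each pair the width in the wild type was subtracted from the width in the knockout. Shares and ratios of peak numbers carry exact Clopper-Pearson 95% intervals, and medians carry exact binomial 95% intervals from order statistics. These intervals cover counting error over peaks only, treat neighbouring peaks as independent, and say nothing about variation between cultures. Intervals of the ratio of knockout to wild-type peak numbers also treat the 2 lists as independent, although most peaks were shared.

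With 1 library per genotype there is no replicate check, and no test between genotypes was made. Differences describe these 2 libraries. The pairing code was run on simulated data with 37667 sites, where it returned a width difference of 240 bp made as 240 bp. A chromosome 4 ratio of 0.684 made as 0.684 was also returned, but it is a plain count of peaks and uses no overlap. The simulated peaks never touched their neighbours, and every knockout peak was widened by the same amount. The simulation therefore checks for coding errors only, and not how the rules act on crowded or shifted peaks.

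The regions to be named were fixed before the data were examined as the 10 top peaks found in each genotype alone, the 5 top shared peaks of each list and the 3 windows of 100 kb with most one-genotype peaks. The planned ranking by fold enrichment or score could not be made because the lists hold neither. Peaks were ranked by width in its place, a choice made after the lists were seen, and ties between windows were broken by chromosome and position. No peak was removed here for lying in repeats or poorly mapped sequence, so the widest regions were not checked for such artifacts. Gene names, promoter shares and the gene lists fixed beforehand were not used here, because the gene table at hand is on GRCm38 and the peaks are on mm9. For the same reason the H2A.Z signal at Anp32e itself was not examined, and the lists hold nothing else that checks the knockout.

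Alternatives to the overlap rule (50% of the shorter peak, 50% of both peaks, a gap of up to 1 kb, centres within 250 bp), merging of peaks within 500 bp, autosomes alone and windows of 500 kb were fixed before the data were examined. Restriction to wide peaks, equal list lengths by width, medians over chromosomes, the omission of 5 chromosomes and bins of 20 and 5 Mb along the chromosomes were added after seeing the data.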

Results

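Genome-wide H2A.Z peaks were compared between 1 wild-type and 1 Anp32e knockout culture of mouse embryonic fibroblasts. The comparison asks whether loss of Anp32e, a chaperone reported to take H2A.Z off chromatin, goes with more or larger H2A.Z-bound regions. The wild-type list held 37667 peaks covering 68.8 Mb, which is 2.68% of the 2.57 Gb between the first and last peaks of the 20 chromosomes listed. The knockout list held 41912 peaks covering 87.4 Mb, or 3.41% of that span. Both lists hold peaks on the 19 autosomes and the X chromosome. There was no replicate of either genotype, and sequencing depth is unknown, so every value below describes these 2 libraries. Intervals cover counting error over peaks only, except those marked as bootstrap.

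H2A.Z peaks were more numerous and wider in the knockout library. It held 4245 more peaks than the wild type, a ratio of 1.11 (95% interval 1.10 to 1.13), and 18.6 Mb more covered sequence, a ratio of 1.27. The median peak was 1881 bp wide in the knockout (quartiles 1445 and 2495 bp) and 1641 bp in the wild type (quartiles 1212 and 2253 bp). Peaks wider than 5 kb numbered 472 in the knockout and 211 in the wild type. Neighbouring peaks lay a median of 14.8 kb apart in the knockout and 16.7 kb apart in the wild type. The excess of peaks was not even over the genome, and chromosome by chromosome the ratio of peak numbers ran from 0.714 to 1.69.

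Most H2A.Z peaks of each list overlapped a peak of the other genotype. Of the wild-type peaks, 30775 overlapped a knockout peak, or 81.7% (95% interval 81.3 to 82.1%). Of the knockout peaks, 30153 overlapped a wild-type peak, or 71.9% (95% interval 71.5 to 72.4%). Circular shifts gave a mean overlap of 6.53% of wild-type and 5.82% of knockout peaks, and no shift exceeded 7.10% or 6.25%. When centres had to lie within 250 bp, the shares were 66.1% of wild-type and 59.4% of knockout peaks. Joined over both lists by the 1 bp rule, the peaks made 48585 regions. Of these, 29934 regions (61.6%) were covered in both genotypes, 11759 (24.2%) in the knockout alone and 6892 (14.2%) in the wild type alone. Regions of the knockout alone therefore outnumbered those of the wild type alone by a factor of 1.71 (95% interval 1.66 to 1.76). The factor was 1.33 when centres had to lie within 250 bp, 1.46 when 50% of both peaks had to overlap and 1.78 when a gap of up to 1 kb was allowed. Filters on width moved it further in both directions, from 1.03 to 7.68, and do not measure it independently because the lists themselves differ in width.

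The extra sequence covered in the knockout lay both in separate peaks and within shared ones. Knockout peaks covered 29.1 Mb that lay outside any wild-type peak. Of this, 18.01 Mb lay in peaks found in the knockout alone and 11.1 Mb within shared peaks. The part within shared peaks holds their flanks and any gaps between wild-type peaks joined by a single knockout peak. Wild-type peaks covered 10.5 Mb outside any knockout peak, with 8.15 Mb in peaks of the wild type alone and 2.33 Mb within shared peaks. The sequence covered in both was 58.3 Mb.

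Shared peaks were wider in the knockout. Among 28979 matched pairs the median width was 2125 bp in the knockout and 1852 bp in the wild type. The median difference within pairs was 215 bp (95% interval 210 to 219 bp, quartiles 41 and 443 bp). The knockout peak was the wider one in 23098 pairs, or 79.7% (95% interval 79.2 to 80.2%). The extension had medians of 93 bp on the side of lower coordinates and 95 bp on the other, while within pairs the centres lay a median of 79.5 bp apart. From the 20% of pairs with the smallest mean width to the 20% with the largest, the median differences were 207, 225, 203, 203 and 238 bp, with no steady trend. Peaks that joined neighbouring sites were also more frequent in the knockout. Its list held 806 peaks that each overlapped 2 or more wild-type peaks (1.92% of the list), whereas 219 wild-type peaks (0.581%) overlapped 2 or more knockout peaks.

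Peaks found in one genotype were narrower than shared peaks in both lists. The median width was 1426 bp for the 11759 knockout-only peaks and 2143 bp for shared knockout peaks. It was 1131 bp for the 6892 wild-type-only peaks and 1840 bp for shared wild-type peaks. Among the narrowest 20% of knockout peaks 60.6% had no partner in the wild type, against 3.58% of the widest 20%. In the wild-type list the corresponding shares were 49.7% and 0.571%.

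**Figure D1:**
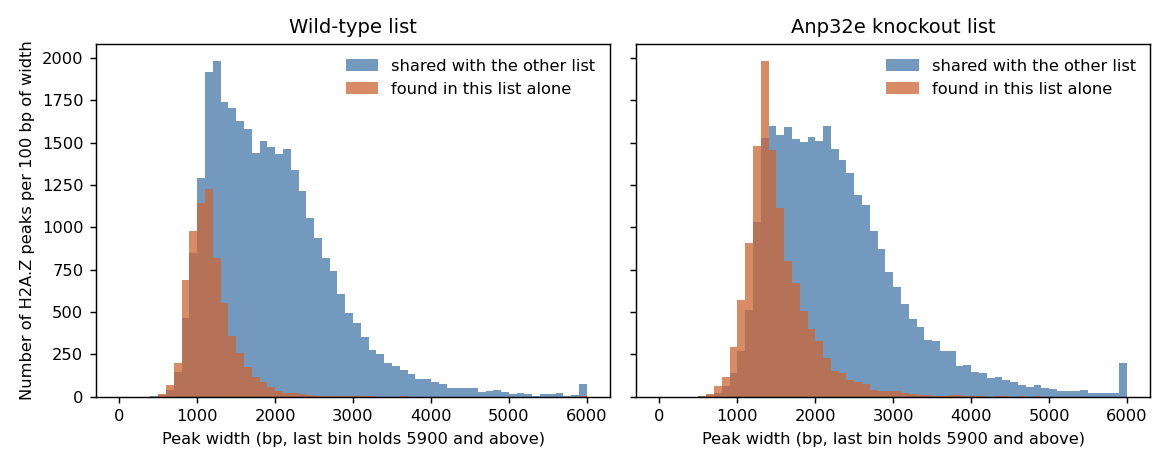
Width of H2A.Z peaks (bp, x axis) against the number of peaks per bin (y axis) in the wild-type list (left) and the Anp32e knockout list (right), with shared peaks in blue and peaks of one list alone in orange. Peaks of one list alone sit at the narrow end in both panels, with medians of 1131 bp in the wild type and 1426 bp in the knockout.

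One-genotype peaks lay nearer to peaks of the other genotype than circularly shifted peaks did. The median knockout-only peak was 10.3 kb from the nearest wild-type peak, and 86.0% lay within 50 kb of one. Circularly shifted peaks that overlapped no wild-type peak lay a median of 56.5 kb away on average, and 47.7% lay within 50 kb. Wild-type-only peaks were a median of 8.31 kb from the nearest knockout peak, against 50.8 kb after shifts. Within 1 kb of a peak of the other list lay 8.33% of knockout-only and 12.03% of wild-type-only peaks. Of shifted peaks without overlap, 2.69% and 3.12% did. Neighbouring peaks within a list were also close, with medians of 16.7 kb in the wild type and 14.8 kb in the knockout. The shifts do not keep peaks in peak-rich sequence, and shared peaks were not compared. These distances therefore do not show a nearness particular to one-genotype peaks.

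The genotypes differed in opposite directions on different chromosomes. Chromosomes 1, 16 and 13 held the largest excess of knockout peaks. On chromosome 1 the knockout had 3260 peaks and the wild type 1925, a ratio of 1.69 (95% interval 1.60 to 1.79). The ratio was 1.59 on chromosome 16 (95% interval 1.48 to 1.72) and 1.44 on chromosome 13 (95% interval 1.36 to 1.53). These 3 chromosomes held 2743 more peaks in the knockout than in the wild type, of the genome-wide net excess of 4245. They carried 28.7% of knockout-only peaks and 17.9% of all knockout peaks.

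On 4 chromosomes the wild type had more peaks and the interval of the ratio lay below 1. Chromosome 4 held 3163 wild-type and 2258 knockout peaks, a ratio of 0.714 (95% interval 0.676 to 0.754). The ratio was 0.803 on chromosome 12, 0.848 on chromosome 6 and 0.893 on chromosome 11. Together these 4 chromosomes carried 38.5% of wild-type-only peaks and 24.7% of all wild-type peaks. On chromosome 4 alone 35.8% of wild-type peaks had no knockout partner, compared with 7.84% on chromosome 1. Chromosomes 14 and 17 had ratios of 1.01 and 0.946 with intervals that included 1, and on the other 14 the interval lay above 1. These intervals ignore that most peaks were shared, so including 1 does not show equal numbers. Chromosome 17 held 384 wild-type-only and 304 knockout-only peaks, and chromosome 14 held 197 and 213. The median of the 20 chromosomes was 1.16 for peak number and 1.29 for covered sequence. Without chromosomes 1, 4, 12, 13 and 16 the pooled ratios were 1.09 and 1.25.

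Peak width followed a similar order of chromosomes. The median difference of matched pairs was 409 bp on chromosome 1, 410.5 bp on chromosome 16 and 354.5 bp on chromosome 13. It was 56 bp on chromosome 12 and 93 bp on chromosome 6, and on chromosome 4 knockout peaks were the narrower ones, by a median of -32 bp (95% interval -44 to -17 bp). The interval lay above 0 on the other 19 chromosomes, and the median of the 20 values was 234 bp. Over the 20 chromosomes the log2 ratio of peak numbers and the width difference had a Pearson r of 0.96 and a Spearman rho of 0.917. With chromosomes 4 and 1 left out r was 0.941. This relation is across chromosomes within a single pair of libraries, and chromosomes are not replicates.

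**Figure D2:**
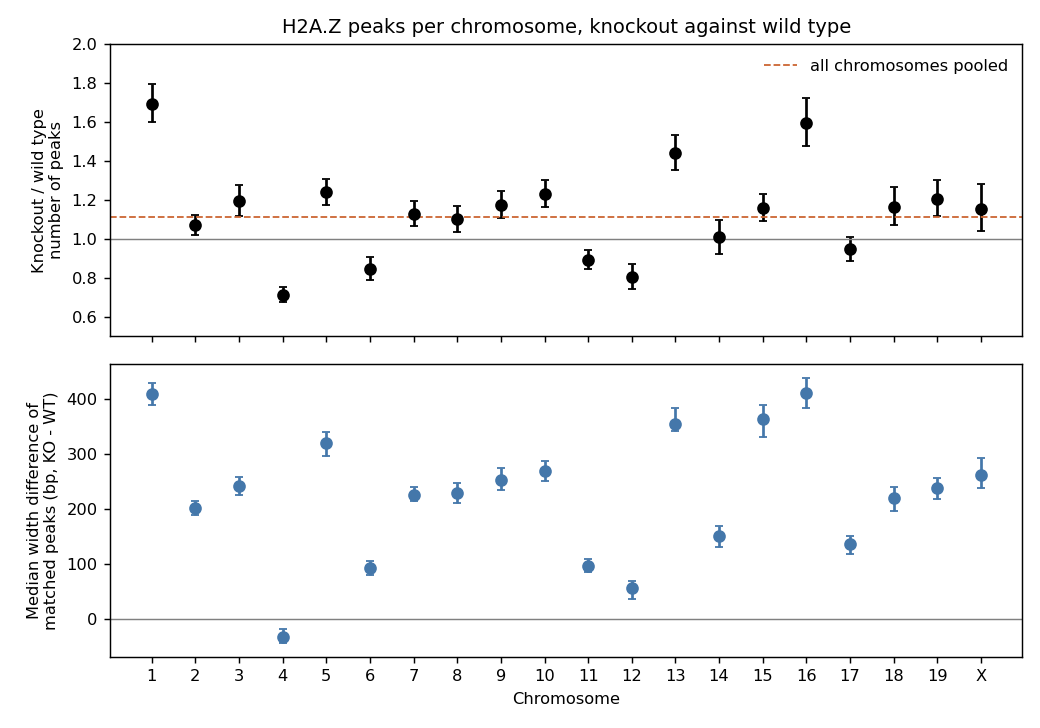
Ratio of the number of H2A.Z peaks in the knockout to that in the wild type (top, with exact 95% intervals; dashed line, all chromosomes pooled) and median width difference of matched peaks in bp (bottom, with 95% intervals) for each chromosome on the x axis. Chromosomes 1 and 16 stand highest and chromosome 4 lowest in both panels.

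**Figure D3:**
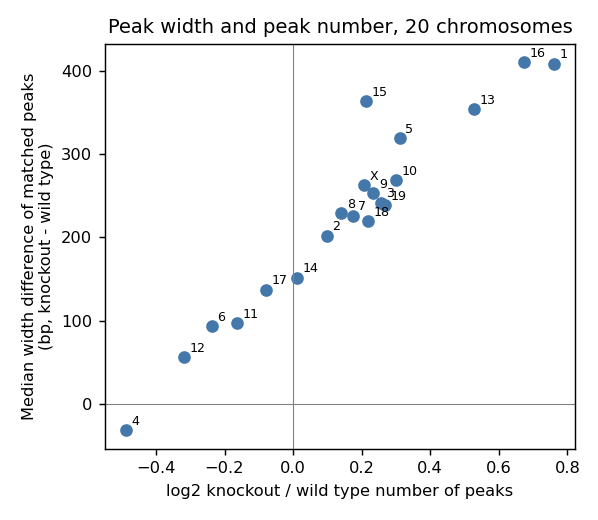
Each point is a chromosome, with the log2 ratio of knockout to wild-type peak number on the x axis and the median width difference of matched peaks (bp) on the y axis. The points rise from chromosome 4 at the lower left to chromosomes 1 and 16 at the upper right, with a Pearson r of 0.96.

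The ratio was similar along the whole of most chromosomes. In bins of 20 Mb it lay between 1.45 and 2.13 in all 10 bins of chromosome 1, between 1.49 and 1.75 in the 5 bins of chromosome 16, and between 0.585 and 0.818 in the 8 bins of chromosome 4. It lay between 1.07 and 1.49 on chromosome 5 and between 1.03 and 1.35 on chromosome 18. Bins with at least 50 peaks of both lists together were kept, and each was weighted by that number for the variance and SD. Chromosome identity accounted for 93.0% of the weighted variance of the log2 ratio over 139 bins. In 1000 shuffles of the bins it accounted for at most 34.6%. Over 413 bins of 5 Mb it accounted for 81.4%, against at most 11.5% after shuffling. The weighted SD of the log2 ratio within chromosomes was 0.15, compared with 0.09 in bins of 20 Mb.

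**Figure D4:**
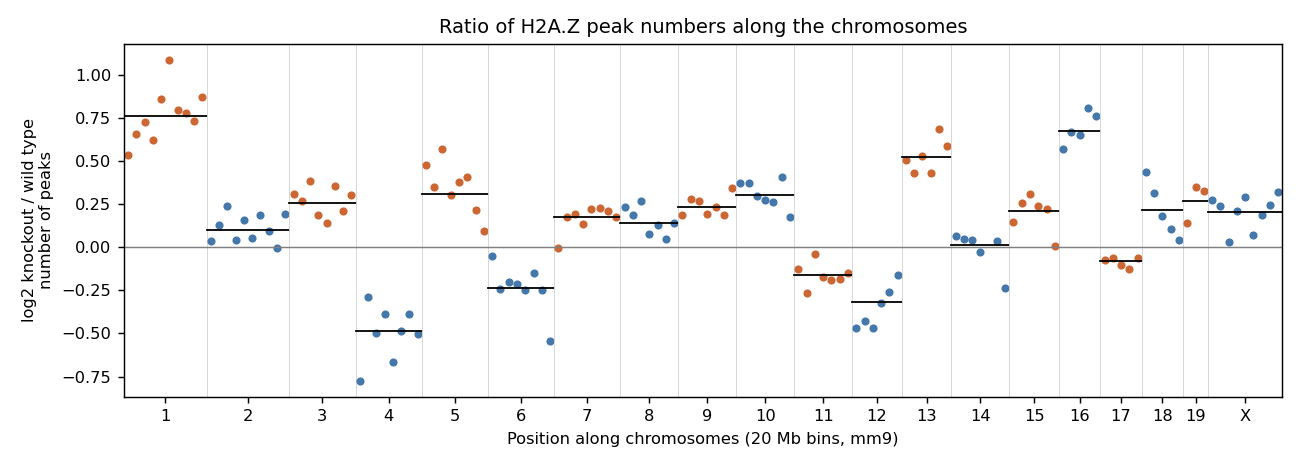
The log2 ratio of knockout to wild-type peak number (y axis) in 20 Mb bins along the chromosomes on mm9 (x axis); points are bins and black lines are the value of the whole chromosome. Bins lie close to the line of their own chromosome, and the lines of chromosomes 1, 4, 13 and 16 lie far from 0.

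All of the 10 widest knockout-only regions were narrower than the 99th percentile of their list, 5109 bp. The first was 5038 bp wide at chromosome 2, 162797724 to 162802761, and lay 21.5 kb from the nearest wild-type peak. It was followed by 4980 bp at chromosome 16, 44493234 to 44498213, and 4823 bp at chromosome 12, 20235616 to 20240438. The next 3 were all on chromosome 15, starting at 100486301, 78298258 and 75953461, with widths of 4819, 4801 and 4606 bp. The remaining 4 of the 10 widest started at 96687653 on chromosome 9, 90267674 on chromosome 8, 97935713 on chromosome 16 and 20276680 on chromosome 7, and were 4605 to 4457 bp wide.

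Among wild-type-only regions, 2 were far wider than the rest. A region of 17562 bp lay near the distal end of the X chromosome, 166420594 to 166438155, with the nearest knockout peak 3.57 kb away. A region of 9186 bp lay at chromosome 1, 90193870 to 90203055, 4.14 kb from the nearest knockout peak. The third was 5513 bp wide at chromosome 17, 3080473 to 3085985. Of the other 7, 4 lay on chromosome 4, starting at 153618526, 44723270, 82182266 and 128695935, and were 5074 to 3773 bp wide. The last 3 started at 96151640 on chromosome 11, 174119668 on chromosome 2 and 75433479 on chromosome 15.

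The widest shared region was the same in both lists, 21702 bp in the knockout (chromosome 1, 90168025 to 90189726) and 20470 bp in the wild type (90169069 to 90189538). Next in the knockout list came a region of 13374 bp at chromosome 15, 98812081 to 98825454, where the wild type had 2 peaks of at most 5480 bp. It was followed by regions of 11229, 11160 and 11080 bp on chromosome 10, starting at 80811274, 76187794 and 79506425, which overlapped 3, 2 and 2 wild-type peaks. Next in the wild-type list came 11251 bp at chromosome 1, 88329831 to 88341081, 8982 bp at chromosome 2, 71376707 to 71385688, and 8535 bp at chromosome 12, 57790262 to 57798796, each divided into 2 peaks in the knockout. The fifth, at chromosome 14, 29316865 to 29325398, was 8534 bp wide with a single knockout partner of 8710 bp.

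One-genotype peaks were counted in windows of 100 kb. No number expected by chance was computed, so neither scatter nor grouping was measured. Windows rich in peaks can hold more one-genotype peaks for that reason alone. Of the 6774 windows of 100 kb that held a knockout-only peak, 4000 held a single one. The highest number was 10, on chromosome 5 at 53800001 to 53900000 and at 118800001 to 118900000. In the first of these the knockout had 11 peaks and the wild type 2. Of 6 windows with 9 knockout-only peaks, the first was chromosome 1, 36600001 to 36700000. Wild-type-only peaks occupied 4668 windows, 3234 of them singly. The 3 windows named by the rule all lay on chromosome 4. Its window from 134500001 to 134600000 held 10 wild-type-only peaks, with 19 wild-type and 10 knockout peaks in all. The windows from 107600001 and from 140900001 held 8 each, as did 3 others in the genome. These 2 were named ahead of the 3 others only by the tie rule of chromosome and position.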

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

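No ratio or difference between the genotypes reversed direction. Shares, counts and widths of a single list have no direction that could reverse. Of 81 alternative values, 46 moved outside the main interval or, for counts, by more than 1.5 times, while 35 did not. The tally includes the ratio of bases covered, for which no interval is given here. Shared shares of wild-type and knockout peaks were 75.8% and 68.1% when 50% of both peaks had to overlap, 66.1% and 59.4% for centres within 250 bp, and 83.9% and 74.3% within 1 kb. Under those rules knockout-only peaks outnumbered wild-type-only ones 1.46, 1.33 and 1.78 times, and wild-type-only peaks numbered 12775 by the centre rule. Within 1 kb, median widths of shared peaks were 1814 bp (wild type) and 2118 bp (knockout). Merging within 500 bp gave a shared knockout share of 72.7%. Windows of 500 kb, being larger, held up to 23 knockout-only and 25 wild-type-only peaks. The following were added after seeing the data. Peaks of at least 1774 bp gave ratios of 1.39 for number and 1.45 for bases, 0.883 on chromosome 4 and 2.03 on chromosome 1. At that width 98.1% of wild-type and 89.5% of knockout peaks were shared, leaving 317 and 2436 alone, a ratio of 7.68; this width keeps 16682 wild-type and 23132 knockout peaks, which by itself raises the ratio. The 18833 widest peaks of each list, set against the full other list, gave 97.4% and 92.5% shared, 488 and 1412 alone, a ratio of 2.89, and 1.15 for bases. Set against the other list cut to the same length, where a partner that was cut counts as absent, they gave 80.5% and 79.8%, 3681 and 3803, and a ratio of 1.03 that equal lengths hold near 1. Medians over chromosomes were 1.16 for number, 1.29 for bases, 84.0% for the shared wild-type share, 1107.5 and 1404 bp for wild-type-only and knockout-only widths and 234 bp for the pair difference. Without chromosomes 1, 4, 12, 13 and 16 the values were 1.09, 1.25, 82.9% and 74.2% shared, and 1.65 for the ratio of one-genotype peaks. Unless stated, the cause was not tested. The planned stricter threshold, equal lengths by score and promoter alternatives were not run, because the lists hold no score and no annotation on mm9 was used. No paired analysis was possible because each genotype has 1 library. Unknown depth limits every comparison of peak numbers and widths.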

Other observations

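Chromosome 15 stood apart in the share of wide peaks in the knockout list, and less clearly in the wild-type list. In the knockout list it held 93 of the 472 peaks wider than 5 kb, which is 19.7% of them, and 5.79% of all knockout peaks. These wide peaks made up 3.84% of its knockout peaks (95% interval 3.11 to 4.68%), against at most 1.65% on any other chromosome, the highest being chromosome 8. In the wild-type list the share on chromosome 15 was 1.43% (95% interval 0.969 to 2.04%), against at most 0.888% elsewhere. That highest other share was on chromosome 11, and its interval of 0.586 to 1.29% overlapped the interval of chromosome 15. Knockout peaks that overlapped 2 or more wild-type peaks made up 3.84% of the list on chromosome 15 and at most 2.33% on the others. The matched-pair difference there was 363.5 bp, close to that of chromosome 13, although its ratio of peak numbers was 1.16.

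The tests in the next paragraphs were chosen after the results were seen, except that of site density, which was chosen before its result was seen. Their bootstrap intervals (1000 resamples) are for values computed across the 20 chromosomes of this single pair of libraries. Chromosomes are not replicates, so these intervals do not measure variation between cultures.

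The ratio of knockout to wild-type peak numbers differed between chromosomes. A single difference in depth or threshold between the libraries is argued against as the whole cause, because 4 chromosomes had a ratio whose interval lay below 1 while the pooled ratio lay above it. The density of H2A.Z sites, used in place of GC and gene content, had little linear relation with the ratio. It accounted for 0.743% of the variance over chromosomes (bootstrap 95% interval 0.00337 to 20.4%). That density was counted from the same 2 lists joined, so it is not independent of the ratio. GC and gene content themselves were not measured and stay open. Local groups of sites are argued against as the whole cause too. Each of the 20 chromosomes was split at its median site into a proximal and a distal part. The log2 ratios of these parts correlated with an r of 0.948 (bootstrap 95% interval 0.900 to 0.976). Such a split does not exclude groups present in both parts or gradients within a chromosome. A whole-chromosome difference in DNA dosage between the 2 cultures, such as an extra or missing chromosome copy arising in culture, is a candidate explanation that stays open, since any chromosome-wide cause gives such a correlation. An effect of the Anp32e genotype cannot be told apart from a difference between these particular cultures, with 1 library per genotype, and the input libraries, which would show DNA dosage directly, were not analysed here.

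Shared peaks were wider in the knockout. A fixed difference set by peak calling is argued against as the whole cause, because the 20 chromosome medians spanned 442.5 bp. Differences between chromosomes are argued against as the whole cause too, since the fitted width difference at a peak number ratio of 1 was 169 bp (bootstrap 95% interval 158 to 186 bp). For that common part a fixed difference set by peak calling, its threshold or its settings stays open. So do greater depth or enrichment of the knockout library, longer fragments, and more H2A.Z on knockout chromatin, as the lists hold no read counts.

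Peaks found in one genotype were narrower than shared peaks. Boundary shifts of the same peak could be tested only in part, because peaks with even 1 bp in common already counted as shared. At most 12.03% of one-genotype peaks lay within 1 kb of the other list, so most were not near misses of that rule. Calls near the threshold of the peak caller and weak sites present in one culture alone both stay open, as the lists hold no score to test them by.

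The widest shared region (chromosome 1, 90168025 to 90189726 in the knockout list) and the wild-type-only region of 9186 bp lay next to each other, 4.14 kb apart measured from the knockout peak. Both exceeded the 99th percentile of width, which was 4524 bp in the wild-type and 5109 bp in the knockout list.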
